A study of Mus musculus with 6 samples.

How the data were processed

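Gene expression was measured in sorted mouse bone marrow stem cells on 6 Affymetrix arrays, 2 in each of 3 groups. The groups were cells carrying an empty GFP vector, cells expressing BCR/ABL, and cells expressing BCR/ABL from mice given imatinib. Group and replicate number were taken from the sample titles. The dose and duration of imatinib are not given in the sources used here.

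The deposited values are linear array intensity values, 1 per probe set, and per the submitters' processing notes they came from Affymetrix Expression Console and MAS5. The versions of these programs are not given in the sources used here. The mean intensity after removal of 2% of the values at each end was 500 on each of the 6 deposited arrays, so each array had been scaled to a common mean. Median intensity ranged from 35.6 to 57.2, and 36.1% to 41.5% of the probe sets on an array lay below 16. Detection calls were not used here, so a low value cannot be separated from background, and the number of arrays limits the precision of each comparison.

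The design text of the series names a whole-transcript array and a labelling kit with random primers. The probe set identifiers of the deposited table and their annotation belong instead to an older 3-prime expression array of the mouse genome. The deposited values are therefore taken as those of that 3-prime array, and the probe sets were used as the table gives them. Which labelling was used is not settled here. Ratios of 3-prime to 5-prime control probe sets depend on the labelling and are given as measured values only.

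The table held 45101 probe sets, of which 64 were named controls and were left out. Gene symbols came from the platform annotation: 34945 probe sets had 1 symbol, 932 had several and 9160 had none. Of the probe sets with 1 symbol, 34741 were matched by Entrez identifier to a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. All 35877 probe sets with at least 1 symbol were tested, with no filter on low values. No gene was named from a probe set with several symbols. For gene lists, each of 18193 genes was represented by its probe set with the highest mean over all arrays. Genome coordinates are not given, because the files name no genome build.

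Values were transformed as log2(value + 16), so fold changes of dim genes are understated and depend on that added constant. The medians of the 6 arrays on this scale ran from 5.69 to 6.19. This exceeded a tolerance of 0.1 fixed before the data were examined, so the values were quantile normalized between arrays. Differences were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes (trend=TRUE). One model covered all 6 arrays, because 2 arrays per group leave 3 residual degrees of freedom, and the prior degrees of freedom were 2.97. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 35877 probe sets of each comparison, with 0.05 as the threshold. The 3 comparisons were BCR/ABL against vector, imatinib against untreated BCR/ABL, and BCR/ABL with imatinib against vector.

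Before the data were examined, 30 gene lists were fixed. They covered BCR and ABL1, the lipoxygenase and leukotriene pathway, stem cell identity, DNA replication and mitosis, cell cycle inhibitors and quiescence, STAT5 targets, RAS and ERK feedback, immediate early and handling stress genes, SRC family kinases, and WNT and Hedgehog signalling. They also covered markers of granulocytes, monocytes and macrophages, B cells, T and NK cells, erythroid cells, megakaryocytes, mast cells and basophils, and stromal and endothelial cells. The remaining lists were interferon response, ribosome biogenesis, glycolysis, hypoxia response, fatty acid and sterol synthesis, p53 targets, BCL2 family, adhesion and homing, cytokines and their receptors, surface genes reported on leukaemic stem cells, drug transporters, and sex-linked genes. Each list was tested with limma's camera at its preset correlation of 0.01, adjusted over the 30 lists of a comparison. Camera with an estimated correlation, and the directional p of fry, which does not compare a list with other genes, were run beside it. Camera with an estimated correlation rests on the model's few residual degrees of freedom. Its p therefore rises even where the estimate is near the preset. Counts of list members are given over all genes tested and adjusted over the list alone.

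Named genes followed a rule fixed before the data were examined. In each comparison these were up to 12 genes that rose and 12 that fell with the largest change among those past the threshold whose groups did not overlap. Where fewer than 10 genes passed, the 20 with the smallest p were given as values only. Members of the fixed lists were named by size of change after any that passed. Genes past the threshold beyond the first 12 were named after their values were seen. With 2 arrays against 2, chance alone separates the groups of 33.3% of genes.

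How far imatinib values returned towards vector was measured by a slope across probe sets. The imatinib change in arrays of one replicate number was regressed on the BCR/ABL change in arrays of the other number, so that no array entered both changes. The slope used probe sets with a BCR/ABL change of at least 1 on the log2 scale and is the mean over both directions. A value of 0 is no return and -1 is full return. Chance values from shared arrays were simulated in 100 draws without any effect, once with equal spread in all groups and once with the replicate spread of each group. The latter was added after the data were seen.

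The test was checked on data simulated for BCR/ABL against vector over 35877 probe sets, in 5 draws with 200 changed probe sets each. It called 20.3% of changes of 1 on the log2 scale, 58.2% of changes of 2 and 89.1% of changes of 4, with at most 4 false calls in a draw. Changed probe sets were drawn from those with a mean signal above the array medians, and the groups had equal spread. These rates therefore need not hold for dim probe sets. The list test called a list shifted by 1 in 20 of 20 draws and made 4 calls in 580 tests of other lists. Genes were simulated as independent of each other, so this check does not cover false calls of lists whose genes are correlated. For a true slope of -0.5 the slope across arrays not shared came out at -0.388, since noise in the BCR/ABL change pulls it towards 0. Each probe set was given an effect drawn with an SD of 1 on the log2 scale, and smaller effects would be pulled further.

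The alternatives were the values as deposited, centring on array medians, filters at the 30th and 50th percentiles of mean signal, all probe sets with or without a symbol, other added constants, other variance models, only the groups compared, the replicate number as a block, and each array left out in turn. Array weights were added after the data were seen. The closing section gives their effect.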

Results

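Transcript levels were measured on 6 Affymetrix arrays in mouse bone marrow stem cells sorted for GFP, absence of lineage markers, c-Kit and Sca-1. BCR/ABL is the fusion tyrosine kinase of chronic myeloid leukaemia, and imatinib inhibits that kinase. The cells carried an empty GFP vector, or expressed BCR/ABL, or expressed BCR/ABL and came from mice given imatinib, with 2 arrays in each group. The purpose named for the series was to find genes that BCR/ABL regulates in these stem cells. The labels do not say whether the 2 arrays of a group came from separate mice. The p-values therefore measure only the spread between these samples, which may be technical.

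The vector arrays differed from each other more than the arrays of the other groups did. Across probe sets, the replicates of a group correlated at 0.971 for vector, 0.991 for BCR/ABL and 0.985 for BCR/ABL with imatinib. More than 2-fold differences between replicates were found for 3694 probe sets in vector, 860 in BCR/ABL and 1611 with imatinib. Vector replicate 2 correlated more closely with an imatinib array, at 0.981, than with vector replicate 1. The 3-prime to 5-prime signal ratio of beta-actin was 1.81 and 1.62 in vector, 1.48 and 1.30 in BCR/ABL, and 1.74 and 1.55 with imatinib. For Gapdh it was 1.56 and 1.37, 1.34 and 1.28, and 1.45 and 1.39 in the same order. Both ratios were lowest in the 2 untreated BCR/ABL arrays.

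The fusion transcript itself was not measured, since mouse Abl1 and Bcr probe sets need not detect a transduced fusion gene. Abl1 changed by -0.63 on the log2 scale in BCR/ABL cells against vector (adjusted p = 0.415) and Bcr by -0.23 (adjusted p = 0.742). The list of BCR, ABL1 and its relative ABL2 had a median change of -0.23, with 3 of 3 members lower and adjusted p = 0.142. These values do not check the labels.

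The first comparison asked which genes differed between BCR/ABL and vector cells. The largest rises in BCR/ABL cells were those of Akr1c18 and Tph1. Akr1c18, a 20-alpha-hydroxysteroid dehydrogenase that inactivates progesterone, had a log2 level of 12.66 ± 0.12 (SD, n = 2) in BCR/ABL cells and 4.36 ± 0.45 in vector cells. Its log2 fold change was 8.30 with a standard error of 0.45 (adjusted p = 0.0152). Its vector level lay close to the floor of 4 that the added constant sets, so the size of this change depends on that constant. Tph1, which catalyses the first step of serotonin synthesis, rose by 5.78 (SE 0.29, adjusted p = 0.0125).

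Among 35877 probe sets, limma called 22 at an adjusted p under 0.05, 21 higher and 1 lower, belonging to 20 genes. The interleukin genes Il6 and Il4 rose by 5.38 (SE 0.46, adjusted p = 0.0421) and 5.17 (SE 0.34, adjusted p = 0.0196). With the replicate number as a block in limma Il6 was not called (adjusted p = 0.0584), nor was Trp53inp1, given below (adjusted p = 0.0734). Cyp11a1, the side-chain cleavage enzyme that begins steroid synthesis, rose by 5.07 (adjusted p = 0.0333). The Akr1c family members Akr1c12 and Akr1c19 rose by 4.93 and 3.25. These paralogs are similar in sequence and 1 called probe set was annotated to both Akr1c12 and Akr1c13, so the separate values are uncertain. Enah, a regulator of actin filaments, rose by 4.66, and its 6 probe sets shared that sign. The adhesion molecule E-cadherin, encoded by Cdh1, rose by 4.33, the protease granzyme B, encoded by Gzmb, by 3.81, the receptor Cd200r3 by 3.48 and the metalloproteinase inhibitor Timp1 by 2.93. Trp53inp1, a p53-induced stress gene, fell by 1.35 (SE 0.12, adjusted p = 0.0470), from 11.79 ± 0.05 to 10.44 ± 0.06. The genes Hdc, Podxl, Plxdc2, Akr1c13, Car4, Perp and Lat were chosen after their values were seen because they complete the set. They rose by between 2.03 for Lat and 2.84 for Plxdc2. In vector, Akr1c19, Timp1 and Car4 lay at 4.05, 4.22 and 4.06, close to the floor of 4. The sizes of their changes therefore depend on the added constant, and their spread in vector is compressed.

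**Figure D1:**
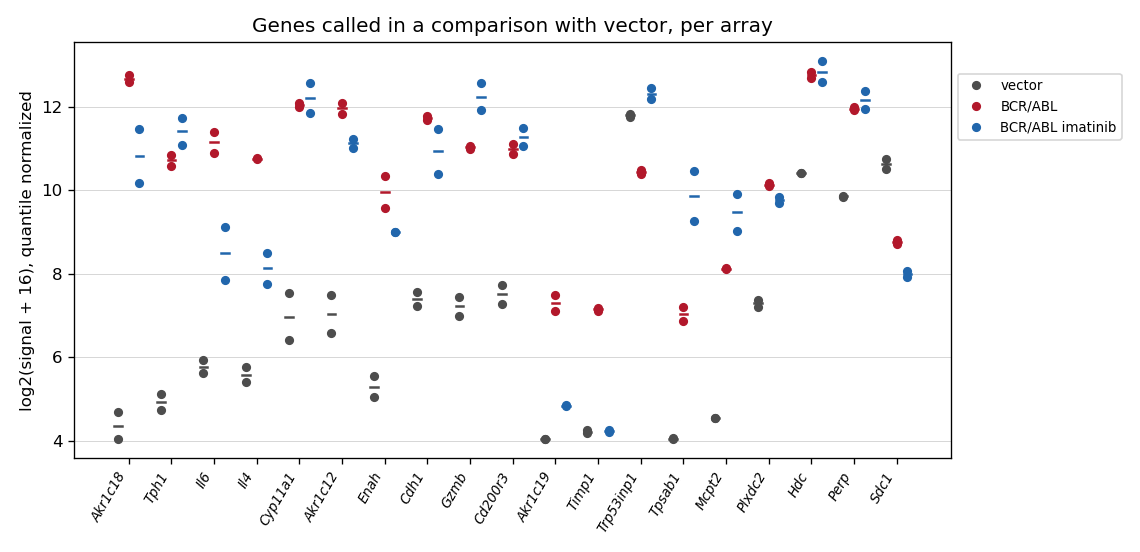
Log2 signal (signal + 16) of the 19 genes with the largest changes among those called in the 2 comparisons with vector, with a point for each array and a bar at each group mean of 2 arrays. Akr1c18, Tph1, Akr1c19, Timp1, Tpsab1 and Mcpt2 are near the floor of 4 to 5 in vector. Trp53inp1 lies lower in untreated BCR/ABL than in both other groups.

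Of the 30 fixed lists, camera called 11, 10 higher and 1 lower, and no call held with an estimated correlation. That loss cannot be put down to gene correlation alone. The lipoxygenase list had an estimated correlation of 0.019, near the preset 0.01. Its unadjusted camera p still went from 4.61e-06 to 0.0218. For megakaryocyte markers, also at 0.019, it went from 0.00123 to 0.0519. Higher estimates in other lists, such as 0.748 for B cell markers, may add to the loss. Mast cell and basophil markers had the lowest p: all 10 measured members were higher, with a median of 2.47 and adjusted p = 1.42e-11. The adjusted p = 0.297 with an estimated correlation. Of these 10, 1 passed over all genes tested, Hdc, the enzyme that makes histamine, with 2.35 (adjusted p = 0.0236), and 9 passed adjusted over the list alone. The largest changes without a call were those of the proteases Tpsb2, 3.61 (adjusted p = 0.374), Cma1, 3.23 (adjusted p = 0.308), and Tpsab1, 2.99 (adjusted p = 0.155). The vector levels of Tpsb2 spread widely, at 7.74 ± 2.94. B cell markers moved the other way: all 13 were lower, with a median of -2.71 (adjusted p = 6.56e-08; adjusted p = 0.539 with an estimated correlation), 0 passed over all genes and 9 adjusted over the list alone. The recombinase gene Rag1 changed by -4.42, the B cell transcription factor gene Ebf1 by -3.20, and the antigen receptor component Cd79a by -3.18 from a vector level of 8.84 ± 2.61. Without vector replicate 1 the B cell median was -1.32.

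The cytokine list had a median of 0.60 over 20 genes, 15 higher and 5 lower (adjusted p = 2.07e-05; adjusted p = 0.297 with an estimated correlation). Il6 passed over all genes, and 10 members rose and 2 fell adjusted over the list alone. Ccl3 and Ccl4, chemokines that attract leukocytes, had changes of 3.68 (adjusted p = 0.0550) and 2.95 (adjusted p = 0.0705), and Il1b one of 3.62 (adjusted p = 0.334). Lipoxygenase and leukotriene genes had a median of 0.71 over 12 genes, 10 higher and 2 lower (adjusted p = 2.77e-05; adjusted p = 0.297 with an estimated correlation). None passed over all genes, and 5 rose adjusted over the list alone. The median was 1.19 above the 50th percentile. Alox5, the enzyme that begins leukotriene synthesis, had a log2 level of 11.27 ± 0.12 in BCR/ABL cells and 7.23 ± 0.90 in vector cells, a change of 4.05 (adjusted p = 0.0778). Ptgs2 changed by 3.11 (adjusted p = 0.350), Alox15 by 2.38 (adjusted p = 0.230) and the leukotriene B4 receptor gene Ltb4r1 by 1.58 (adjusted p = 0.1).

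Targets of STAT5, a transcription factor downstream of the kinase, had a median of 0.48 over 16 genes (adjusted p = 0.000135; adjusted p = 0.379 with an estimated correlation). Of these, 0 passed over all genes, while 8 rose and 1, Bcl6, fell adjusted over the list alone. Il2ra changed by 3.59, Osm by 3.16 (adjusted p = 0.0705), Cish by 2.39, and Bcl6, which STAT5 represses, by -1.32. RAS and ERK feedback genes had a median of 0.45 over 15 genes (adjusted p = 0.00486; adjusted p = 0.623 with an estimated correlation), with 0 calls over all genes and 4 higher and 1 lower adjusted over the list alone. Phlda1 changed by 3.06, Fosl1 by 2.42 and Emp1, the member that fell, by -1.58. Restriction to probe sets above the 50th percentile ended this list's call (median 0.33, adjusted p = 0.130). The median was 0.73 with the probe sets of a gene averaged, and 0.69 with array medians, or 0.48 relative to all genes.

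Glycolysis genes had a median of 0.37, with 13 of 13 higher (adjusted p = 1.68e-07; adjusted p = 0.311 with an estimated correlation), 0 calls over all genes and 7 adjusted over the list alone. The lactate exporter Slc16a3 changed by 2.59 (adjusted p = 0.119) and the glucose transporters Slc2a1 and Slc2a3 by 0.71 and 0.66. The hypoxia list had a median of 0.43 over 15 genes (adjusted p = 0.0198; adjusted p = 0.623 with an estimated correlation), with 0 calls over all genes and 3 adjusted over the list alone, among them Bhlhe40 at 3.37 and Bnip3 at 1.03. Its call ended without vector replicate 1 (median 0.24, adjusted p = 0.205), and the median was 0.66 without vector replicate 2. Averaging the probe sets of a gene also ended it (adjusted p = 0.0761). The p53 target list had a median of 0.97 over 13 genes, 10 higher and 3 lower (adjusted p = 0.0317; adjusted p = 0.623 with an estimated correlation). Trp53inp1, the member that passed over all genes, went against the list, while Eda2r, Cdkn1a and Plk2, at 1.56, 1.33 and 1.25, passed adjusted over the list alone. This call ended without vector replicate 1 (adjusted p = 0.164), vector replicate 2 (adjusted p = 0.0583) or BCR/ABL replicate 1 (adjusted p = 0.164), with array medians (adjusted p = 0.144) and above the 50th percentile (median 0.29, adjusted p = 0.266), and the median was 0.61 with the probe sets of a gene averaged.

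Megakaryocyte markers had a median of 0.98 over 9 genes (adjusted p = 0.00486; adjusted p = 0.311 with an estimated correlation), with 0 calls over all genes and 4 adjusted over the list alone, among them the integrins Itga2b at 1.32 and Itgb3 at 1.24. Without vector replicate 1 the median was 0.59. Granulocyte markers had a median of 0.58 over 15 genes (adjusted p = 0.00534; adjusted p = 0.539 with an estimated correlation), and 0 passed over all genes or over the list alone. Ltf, a granule protein, changed by 2.62 from a vector level of 9.5 ± 3.12. The granulocyte median was 1.14 without vector replicate 1 and 0.31 without vector replicate 2, and the call ended without BCR/ABL replicate 2 (adjusted p = 0.153). The 2 vector arrays thus stood apart in the same lists: centred on all 6 arrays, the median B cell marker lay at 3.45 and 0.65 in vector replicates 1 and 2, and the median mast cell marker at -1.15 and -2.25.

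**Figure D2:**
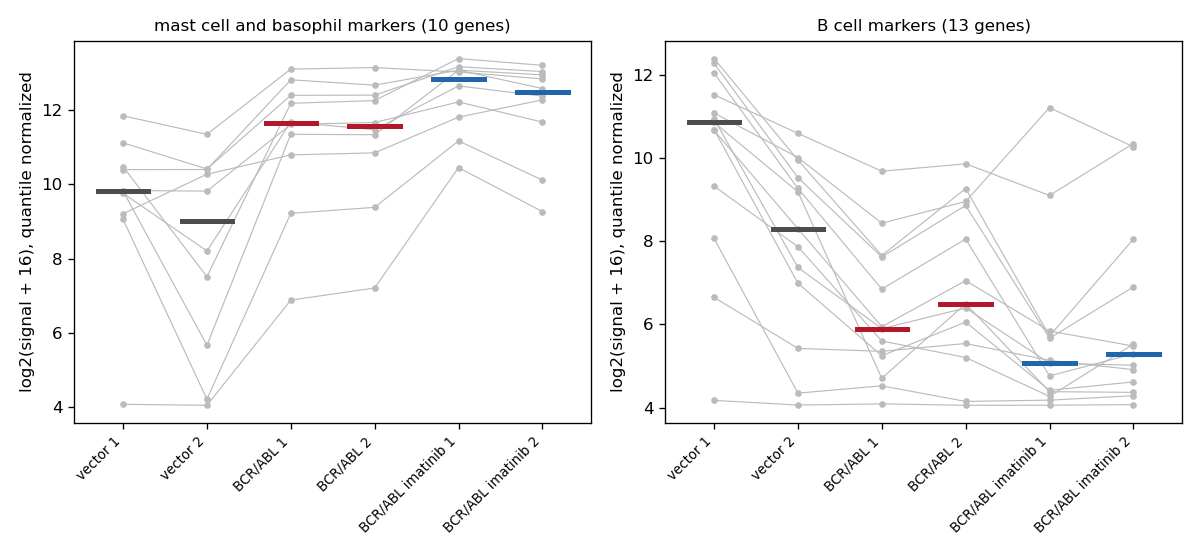
Log2 signal of mast cell and basophil markers (10 genes) and B cell markers (13 genes) on each of the 6 arrays. A grey line marks each gene and a coloured bar the list median of each array. The plotted values are not centred, so the centred medians given next cannot be read off the panels. With each gene centred on its mean over the 6 arrays, mast cell medians are -1.15 and -2.25 in vector, 0.52 and 0.53 in BCR/ABL, and 1.36 and 1.31 with imatinib. Centred B cell medians are highest in vector replicate 1, at 3.45.

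The lists not called in this comparison included stem cell identity, with a median of -0.01 (adjusted p = 0.980), where the mean of 0.07 had the opposite sign. In it Thy1, a surface glycoprotein, changed by 2.81 (adjusted p = 0.0705). DNA replication and mitosis genes had a median of -0.09 (adjusted p = 0.0914), cell cycle inhibitors -0.06 with a mean of 0.24 (adjusted p = 0.792), ribosome biogenesis 0.14 (adjusted p = 0.102), interferon response 0.29 (adjusted p = 0.365), adhesion and homing 0.03 (adjusted p = 0.980), surface genes reported on leukaemic stem cells 0.28 (adjusted p = 0.492) and drug transporters 0.31 (adjusted p = 0.120). Leaving out 1 array brought some calls: without BCR/ABL replicate 2 the interferon median was 0.84 (adjusted p = 0.000325) and that of DNA replication -0.15 (adjusted p = 0.0117). Without BCR/ABL replicate 1 ribosome biogenesis was called at 0.19 (adjusted p = 0.0263), and the interferon median was 0.02. Without vector replicate 2 DNA replication was called at -0.12 (adjusted p = 0.0416) and drug transporters at 0.48 (adjusted p = 0.0336), the latter also with the probe sets of a gene averaged (adjusted p = 0.0464).

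Several lists were called in none of the 3 comparisons as tested, and their values here are for BCR/ABL against vector. Medians were 0.15 for SRC family kinases (adjusted p = 0.980, with a test direction opposite to the median), -0.11 for WNT and Hedgehog signalling (adjusted p = 0.120), 0.23 for monocyte and macrophage markers (adjusted p = 0.980), -0.86 for T and NK cell markers (adjusted p = 0.130), of which Gzmb rose, and 0.02 for erythroid markers (adjusted p = 0.980). The monocyte median was -0.57 and called lower without vector replicate 2 (adjusted p = 0.0416), and 1.17 and called higher without vector replicate 1 (adjusted p = 0.0173). The erythroid median was 0.45 and called higher without vector replicate 1 (adjusted p = 0.00197), and -0.50 without vector replicate 2 (adjusted p = 0.0638). WNT and Hedgehog signalling was called lower without BCR/ABL replicate 1 (median -0.34, adjusted p = 0.0244) and above the 50th percentile (median -0.37, adjusted p = 0.0206). The T and NK cell median was -1.29 and called lower without vector replicate 2 (adjusted p = 0.00222), called lower with array medians too, and 1.41 and not called above the 50th percentile. Other medians were 0.09 for stromal and endothelial markers (adjusted p = 0.893), -0.07 for fatty acid and sterol synthesis with a mean of 0.04 (adjusted p = 0.980), -0.05 for the BCL2 family (adjusted p = 0.833) and -0.03 for sex-linked genes (adjusted p = 0.792). Immediate early and handling stress genes had a median of -0.003 and a mean of 0.23 (adjusted p = 0.980). Relative to the median of all genes, which the scalings themselves moved, the sign of the median turned under another scaling for stem cell identity, SRC kinases, and erythroid and stromal markers. For BCR and ABL1, DNA replication, cell cycle inhibitors, fatty acid synthesis, the BCL2 family, sex-linked and immediate early genes it turned only with that shift of all genes.

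The count of 22 fell to 0 without BCR/ABL replicate 1 or 2 or with a variance prior not tied to signal, and to 2 without vector replicate 2, while it was 38 without vector replicate 1. It rose to 298, with 265 higher and 33 lower, after centring on array medians, to 189 and 132 with filters at the 30th and 50th percentiles, to 83 with 1 as the added constant, and to 42 with a robust prior.

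The second comparison asked what imatinib changed in BCR/ABL cells. Camera at its preset correlation called ribosome biogenesis, glycolysis and DNA replication genes lower with imatinib, and cell cycle inhibitors and stem cell genes higher. These calls rest on whole lists, with adjusted p = 0.722 for each with an estimated correlation. No single gene passed: limma called 0 of 35877 probe sets, and the smallest adjusted p was 0.0815. At an unadjusted p under 0.05 there were 5238 probe sets, 2246 higher and 2992 lower, where 1794 would arise by chance.

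Among the 20 genes with the smallest p, none of which passed, Trp53inp1 had a log2 level of 12.31 ± 0.20 (SD, n = 2) with imatinib and 10.44 ± 0.06 without, a change of 1.87 (SE 0.12, adjusted p = 0.0815). Values for the co-receptor Nrp1 were -2.38 (SE 0.16), for Timp1 -2.91, for the carbonic anhydrase Car4 -2.45, for the spermidine synthase gene Srm -1.24 and for the nucleolar protein gene Lyar -1.13, each with adjusted p = 0.0815. Timp1 and Car4 lay at 4.24 and 4.05 with imatinib, close to the floor, as did Aldh1a3 at 4.07 and Ccl24 at 4.375, whose changes follow. The phosphodiesterase gene Pde4b changed by 1.21, but 3 of its 6 probe sets shared that sign. The other changes were 2.52 for Slc15a2, 1.92 for Ypel3, 1.83 for Ago4, 1.34 for Mfge8, 1.24 for Pink1, 0.94 for Cdkn1b, -0.73 for the cytochrome c gene Cycs, -1.21 for Lap3, -1.26 for Podxl, -1.44 for Lman1, -2.21 for Aldh1a3, -2.46 for Parm1 and -3.37 for the chemokine gene Ccl24, with adjusted p of 0.0998 for Slc15a2 and 0.102 for the rest. On the brightest probe sets of Lman1 and Aldh1a3 the changes were smaller, at -0.401 and -0.518, and 4 of 5 Lman1 probe sets shared the sign.

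Camera called 9 lists, 4 higher and 5 lower. With an estimated correlation the adjusted p = 0.722 for each of them, and fry called none. Ribosome biogenesis had the lowest p: 16 of 16 genes were lower, with a median of -0.51 and adjusted p = 1.54e-11, and 13 of them fell adjusted over the list alone, with 0 over all genes. Rrp12 changed by -1.29 (adjusted p = 0.159), Bop1 by -1.24 (adjusted p = 0.108) and Nop2 by -0.82. Glycolysis genes had a median of -0.41 (adjusted p = 0.00128), with 11 of 13 lower and 6 falling adjusted over the list alone, among them Slc16a3 at -1.15, Pfkp at -0.72 and Tpi1 at -0.53. DNA replication and mitosis genes had a median of -0.24 (adjusted p = 8.78e-05), with 26 of 28 lower but 0 called over the list alone. The thymidylate synthase gene Tyms changed by -1.65, Ccne1 by -1.07 and the mitotic kinase gene Plk1 by -0.93. This median was -0.04 without imatinib replicate 2, -0.45 without imatinib replicate 1 and -0.37 without BCR/ABL replicate 1. With array medians the medians were -0.59 for DNA replication, -0.87 for ribosome biogenesis and -0.73 for glycolysis, or -0.32, -0.60 and -0.46 relative to all genes.

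RAS and ERK feedback genes had a median of -0.35 over 15 genes (adjusted p = 0.0139), with 13 lower and 3 falling adjusted over the list alone. Phlda1 changed by -3.06 and Spry4, an inhibitor of the pathway, by -1.77. The call ended without BCR/ABL replicate 1 (median -0.23, adjusted p = 0.150), without imatinib replicate 2 (median -0.04, adjusted p = 0.470) and above the 50th percentile (adjusted p = 0.202), and the median was -0.72 without imatinib replicate 1 and -0.56 without BCR/ABL replicate 2. With array medians it was -0.61, or -0.34 relative to all genes. Interferon response genes had a median of -0.72 over 15 genes (adjusted p = 0.00940), with 13 lower and 2 falling adjusted over the list alone. The chemokine gene Cxcl10 changed by -2.95 (adjusted p = 0.121), and Mx1 by -0.997 from an untreated level of 9.94 ± 1.60. This call ended without BCR/ABL replicate 1 (median -0.15, adjusted p = 0.553) and without imatinib replicate 1 (median -0.54, adjusted p = 0.223), and the median was -0.43 with the values as deposited. Centred on all 6 arrays, the interferon median was 0.85 in BCR/ABL replicate 1 and -0.17 in BCR/ABL replicate 2.

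Cell cycle inhibitors and quiescence genes had a median of 0.49 over 17 genes (adjusted p = 0.00154), with 13 higher. Adjusted over the list alone 8 rose and 1, Cdkn2b, fell; their values were 1.32 for Ccng2, 1.08 for Tob1, 0.94 for Cdkn1b, which encodes the kinase inhibitor p27, and -1.91 for Cdkn2b. Without imatinib replicate 1 the adjusted p was 0.0628. Stem cell identity genes had a median of 0.39 over 27 genes (adjusted p = 0.00189), with 24 higher. Only Kit, the receptor used in the sort, passed adjusted over the list alone, with a change of 1.14 (adjusted p = 0.108 over all genes), and Flt3 changed by 1.36. Mast cells also carry c-Kit, and their markers were higher in this comparison too (median 1.01). Without imatinib replicate 2 the median was 0.28 (adjusted p = 0.0974). With array medians, which shift all genes, their medians were 0.17 and 0.12, or 0.44 and 0.39 relative to all genes.

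Mast cell and basophil markers had a median of 1.01 over 10 genes (adjusted p = 0.00873), with 9 higher and only Tpsab1, at 2.82, rising adjusted over the list alone. Megakaryocyte markers had a median of 0.80 over 9 genes (adjusted p = 0.00940), with 8 higher and 3 rising adjusted over the list alone, namely Vwf at 1.28, Itgb3 at 1.11 and Pf4 at 0.80. Without imatinib replicate 1 the mast cell median was 0.81 (adjusted p = 0.175) and the megakaryocyte median 0.67 (adjusted p = 0.0829). With array medians they were 0.62 and 0.44, or 0.896 and 0.715 relative to all genes.

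**Figure D3:**
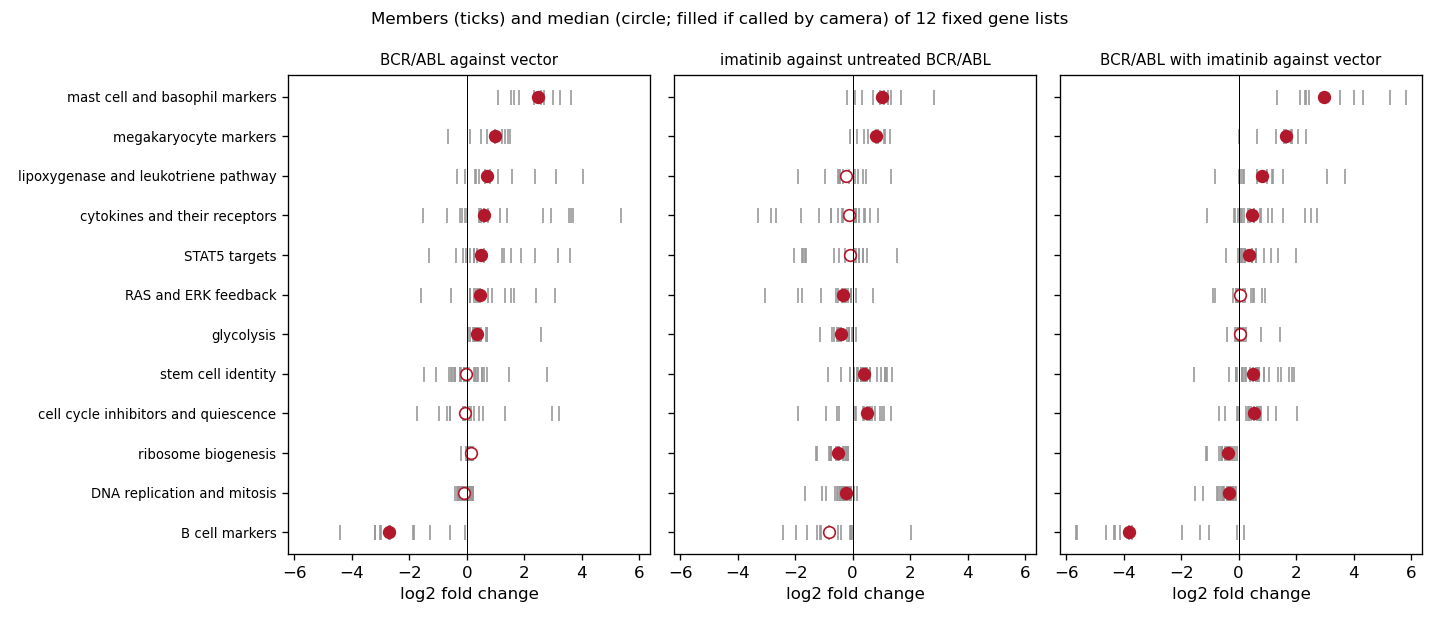
Log2 fold changes of the members of 12 of the fixed lists in the 3 comparisons, with a tick for each gene and a circle at the list median, filled where camera called the list at its preset correlation. Mast cell medians are 2.47, 1.01 and 2.99, and ribosome biogenesis medians 0.14, -0.51 and -0.37, for BCR/ABL against vector, imatinib against untreated BCR/ABL, and BCR/ABL with imatinib against vector.

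Several lists that were higher in BCR/ABL cells were not called with imatinib. STAT5 targets had a median of -0.10 (adjusted p = 0.297), with 1 gene higher, Bcl6 at 1.55, and 4 lower adjusted over the list alone. Osm changed by -2.04 (adjusted p = 0.108), Cish by -1.77 and Id1 by -1.73. Cytokines had a median of -0.15 (adjusted p = 0.293), with 1 higher and 3 lower adjusted over the list alone. Il6 changed by -2.66 (adjusted p = 0.120) and Il1b by -3.29. Lipoxygenase genes had a median of -0.23 (adjusted p = 0.780). Alox5 was at 10.31 ± 0.65 with imatinib, a change of -0.97 (adjusted p = 0.432), and Alox15 changed by 1.33. The hypoxia list had a median of -0.17 with the test pointing the other way (adjusted p = 0.962), p53 targets -0.004 with a mean of 0.09 (adjusted p = 0.455), and adhesion and homing 0.15 (adjusted p = 0.0665). Relative to all genes, p53 targets changed sign under another scaling, and adhesion genes only with the shift of all genes. Adhesion was called without BCR/ABL replicate 2 (median 0.19, adjusted p = 0.0193). Fatty acid and sterol synthesis had a median of -0.01 (adjusted p = 0.297), with 4 lower adjusted over the list alone, such as Idi1 at -1.14, Fdps at -1.13 and Fasn at -0.99. It was called lower with array medians (median -0.38, or -0.104 relative to all genes, adjusted p = 0.0193). B cell markers, at -0.84 and not called (adjusted p = 0.297), were called lower with only the 2 groups compared (adjusted p = 0.0337) and without vector replicate 1 (adjusted p = 0.0418). In the BCL2 family Bcl2l11, which encodes the death-promoting protein BIM, changed by 1.64 (adjusted p = 0.108).

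**Figure D4:**
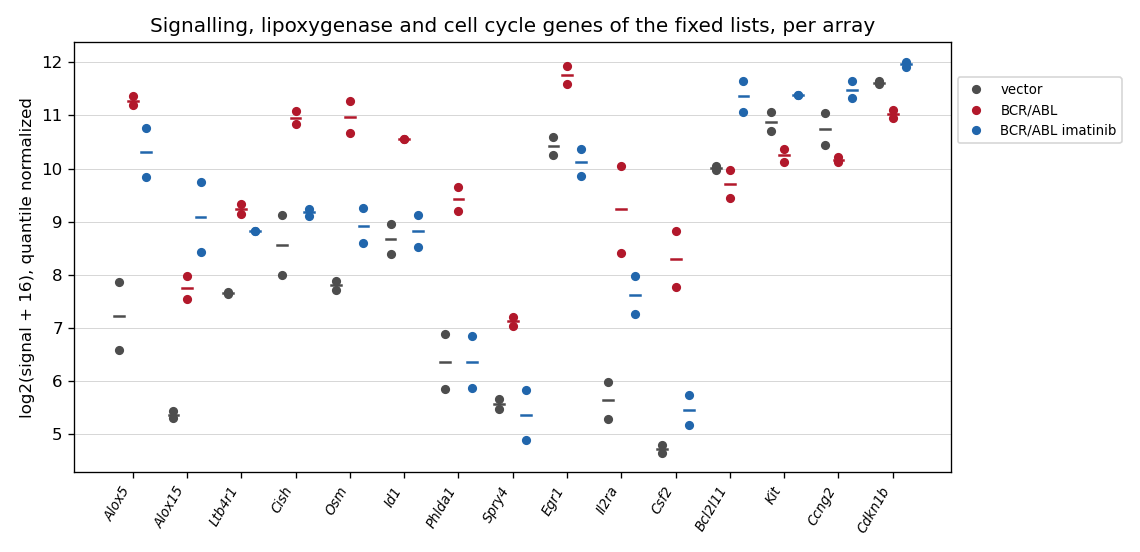
Log2 signal (signal + 16) on each array of 15 members of the fixed lists, chosen after their values were seen, with a bar at each group mean of 2 arrays. Alox5 lies at 7.23 in vector, 11.27 in BCR/ABL and 10.31 with imatinib, and Cish, Osm, Id1 and Phlda1 are higher in untreated BCR/ABL than in both other groups.

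The count of 0 in this comparison depended on the scaling and filter: centring on array medians gave 1200 calls, 67 higher and 1133 lower, and filters at the 30th and 50th percentiles gave 142 (45 higher and 97 lower) and 211 (79 higher and 132 lower). It was 17 with array weights, a setting added after the data were seen, and centring on array medians moved the median of all genes to 0.20 in BCR/ABL against vector and to -0.27 with imatinib against untreated BCR/ABL.

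The return of imatinib-treated cells towards vector was measured across probe sets that differed by at least 1 between BCR/ABL and vector. The slope was -0.10, where -1 is full return, and was -0.101 and -0.102 in the 2 directions, over 5015 and 1889 probe sets. Of these, 58.3% and 56.6% changed in the opposite direction with imatinib. Simulation without any effect gave a slope of -0.00101 with the replicate spread of each group and -6.44e-05 with equal spread. When the BCR/ABL arrays entered both changes the slope was -0.288, against -0.246 simulated without effect with the replicate spread of each group and -0.501 with equal spread. Probe sets are not independent replicates, so no p is given. Noise in the BCR/ABL change pulls the slope across arrays not shared towards 0. The size of that pull was not measured for these data, so the return may be understated.

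The last comparison set BCR/ABL cells from imatinib-treated mice against vector cells. Of the 22 probe sets called in the first comparison 13 were again called higher, and the mast cell protease genes Tpsab1 and Mcpt2 joined them. Tph1 had a log2 level of 11.40 ± 0.46 (SD, n = 2) with imatinib and 4.93 ± 0.26 in vector, a rise of 6.48 (SE 0.29, adjusted p = 0.0193). Akr1c18 rose by 6.46 (SE 0.45, adjusted p = 0.0363). Of 35877 probe sets 16 were called, 15 higher and 1 lower, belonging to 15 genes.

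The mast cell protease genes Tpsab1 and Mcpt2 rose by 5.81 (SE 0.49, adjusted p = 0.0484) and 4.91 (SE 0.40, adjusted p = 0.0423). With the replicate number as a block in limma neither was called (adjusted p = 0.0998 and 0.0833). Both have paralogs of similar sequence. In vector, Tpsab1 lay at 4.05 and Mcpt2 at 4.55, close to the floor of 4, so the sizes of these rises depend on the added constant. Cyp11a1 rose by 5.24 (adjusted p = 0.0369), Gzmb by 5.02 (adjusted p = 0.0194), Akr1c12 by 4.10, Enah by 3.84 on another of its probe sets than the 4.66 above (4.42 in BCR/ABL cells on this one), Cd200r3 by 3.77, Plxdc2 by 2.48, Hdc by 2.44 and Perp by 2.31. Sdc1, a heparan sulphate proteoglycan of the cell surface, fell by 2.64 (SE 0.19, adjusted p = 0.0363), from 10.63 ± 0.16 to 7.99 ± 0.11. Akr1c13 and Podxl, named after their values were seen, rose by 2.10 and 1.53. Across both comparisons with vector, 13 probe sets were called higher in both, those of Akr1c12, Akr1c13, Akr1c18, Cd200r3, Cyp11a1, Enah, Gzmb, Hdc, Perp, Plxdc2, Podxl and Tph1 and 1 shared by Akr1c12 and Akr1c13, and 0 were called lower in both. Independent lists would share 0.00878 higher, and 100 simulated draws without effect shared 0.01 on average with equal spread and 0 with the replicate spread of each group. Without any effect hardly any probe set is called. These draws therefore do not show how much of the overlap comes from the shared vector arrays. The correlation of both changes across probe sets was 0.631, against 0.707 simulated without effect with the replicate spread of each group and 0.499 with equal spread. The covariance was 0.18, against 0.11 and 0.0669. The observed correlation thus lay between the 2 simulated values and the covariance above both. The 2 vector arrays cannot be split so that each part keeps 2.

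Camera called 16 lists, 13 higher and 3 lower, none of them with an estimated correlation. Mast cell and basophil markers had a median of 2.99 with 10 of 10 higher (adjusted p = 1.15e-13; adjusted p = 0.332 with an estimated correlation). Tpsab1 and Hdc passed over all genes, and 10 of 10 adjusted over the list alone, with Tpsb2 at 5.28, Cma1 at 4.31 and the IgE receptor gene Fcer1a at 3.54. Megakaryocyte markers had a median of 1.66 with 9 of 9 higher (adjusted p = 5.03e-06; adjusted p = 0.332 with an estimated correlation), and 5 rose adjusted over the list alone, among them Itgb3 at 2.34 (adjusted p = 0.0805), Gp9 at 2.06 and Pf4 at 1.30. B cell markers had a median of -3.82 with 12 of 13 lower (adjusted p = 1.04e-07; adjusted p = 0.336 with an estimated correlation) and 9 falling adjusted over the list alone. Rag1 changed by -5.64 and Ebf1 by -5.63, while the interleukin 7 receptor gene Il7r, the exception, changed by 0.19. Without vector replicate 1 this median was -2.47.

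Ribosome biogenesis genes were below vector, with a median of -0.37, 16 of 16 lower (adjusted p = 7.01e-10; adjusted p = 0.332 with an estimated correlation) and 11 falling adjusted over the list alone, such as Bop1 at -1.11. DNA replication and mitosis genes had a median of -0.33 with 28 of 28 lower (adjusted p = 1.29e-09; adjusted p = 0.336 with an estimated correlation) and 2 falling adjusted over the list alone, and Tyms changed by -1.53. Without imatinib replicate 2 this median was -0.20. Cell cycle inhibitors had a median of 0.54 (adjusted p = 0.000195; adjusted p = 0.332 with an estimated correlation), with 13 of 17 higher, 6 of them adjusted over the list alone, and 0.35 without vector replicate 2. The p53 targets had a median of 0.52 with 13 of 13 higher (adjusted p = 0.000195; adjusted p = 0.336 with an estimated correlation), 2 of them adjusted over the list alone, and 0.34 without imatinib replicate 1.

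Lipoxygenase genes had a median of 0.81 over 12 genes (adjusted p = 0.000442; adjusted p = 0.332 with an estimated correlation), with 5 rising adjusted over the list alone, Alox15 at 3.71 (adjusted p = 0.116) and Alox5 at 3.08 (adjusted p = 0.127). It was 0.45 without imatinib replicate 1. Cytokines had a median of 0.47 over 20 genes (adjusted p = 0.000442; adjusted p = 0.332 with an estimated correlation), with 7 rising and 1 falling adjusted over the list alone, and Il6 changed by 2.71. STAT5 targets had a median of 0.35 over 16 genes (adjusted p = 0.00220; adjusted p = 0.336 with an estimated correlation), with Socs2 at 1.37 the member that rose adjusted over the list alone, and 0.18 without vector replicate 1. With array medians it was 0.23, or 0.317 relative to all genes.

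Stem cell identity had a median of 0.50 over 27 genes (adjusted p = 0.000442; adjusted p = 0.430 with an estimated correlation), with Thy1 at 1.93 and 2 others rising adjusted over the list alone. Its call ended without vector replicate 1 (median 0.12, adjusted p = 0.107) and imatinib replicate 2 (median 0.31, adjusted p = 0.0702). Granulocyte markers had a median of 0.65 over 15 genes (adjusted p = 0.00220; adjusted p = 0.336 with an estimated correlation), 0 of them adjusted over the list alone. Their median was 1.23 without vector replicate 1 and 0.36 without vector replicate 2, and the call ended without imatinib replicate 2 (adjusted p = 0.0638). The hypoxia list had a median of 0.35 over 15 genes (adjusted p = 0.00370; adjusted p = 0.336 with an estimated correlation), with 6 rising adjusted over the list alone, among them Ddit4 at 2.14 and Ndrg1 at 1.37. It was 0.10 without imatinib replicate 1 (adjusted p = 0.0634), 0.58 without imatinib replicate 2 and 0.57 without vector replicate 2.

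Surface genes reported on leukaemic stem cells had a median of 0.43 over 12 genes (adjusted p = 0.00573; adjusted p = 0.336 with an estimated correlation), with Itga2 at 1.87 and Cd9 at 0.81 rising adjusted over the list alone. The median was 0.92 without vector replicate 1, and the call ended without vector replicate 2 (median 0.28, adjusted p = 0.315). Drug transporters had a median of 0.38 over 8 genes (adjusted p = 0.0246; adjusted p = 0.336 with an estimated correlation) with 0 adjusted over the list alone, and adhesion and homing 0.21 over 16 genes (adjusted p = 0.0376; adjusted p = 0.356 with an estimated correlation), with the chemokine receptor genes Ccr1 at 2.46 and Cxcr2 at 1.49 among 3 that rose adjusted over the list alone. The transporter call ended above the 50th percentile (adjusted p = 0.179) and without vector replicate 1 (median 0.09, adjusted p = 0.200), imatinib replicate 1 (adjusted p = 0.0613) or imatinib replicate 2 (adjusted p = 0.0645). The adhesion call ended under 7 of 14 settings, among them the values as deposited (adjusted p = 0.111), array medians (adjusted p = 0.139), vector replicate 2 left out (adjusted p = 0.263) and imatinib replicate 2 left out (adjusted p = 0.0742). Glycolysis, with a median of 0.04 (adjusted p = 0.172), RAS and ERK feedback, 0.04 (adjusted p = 0.840), and interferon response, -0.39 (adjusted p = 0.0578), were not called against vector. Interferon response was called lower under 7 of 14 settings, namely the replicate number as a block (adjusted p = 0.0326), a variance prior not tied to signal (adjusted p = 0.0486), only the 2 groups compared (adjusted p = 0.0480), the probe sets of a gene averaged (adjusted p = 0.0338), and BCR/ABL replicate 1 (adjusted p = 0.0459), BCR/ABL replicate 2 (adjusted p = 0.0449) or imatinib replicate 2 (median -0.33, adjusted p = 0.0115) left out. Glycolysis was called at 0.21 without imatinib replicate 2 (adjusted p = 0.0161). Relative to all genes glycolysis changed sign under another scaling, and RAS and ERK feedback only with the shift of all genes. Fatty acid and sterol synthesis, at -0.18 and not called (adjusted p = 0.0631), was called lower with the values as deposited (adjusted p = 0.0144), array medians (adjusted p = 0.0135), a variance prior not tied to signal (adjusted p = 0.0486) and the probe sets of a gene averaged (adjusted p = 0.0369). Erythroid markers, at 0.07 (adjusted p = 0.490), were called higher without vector replicate 1 (median 0.41, adjusted p = 0.000789). Without vector replicate 2 monocyte and macrophage markers, at -0.38 (adjusted p = 0.451), were called lower (median -0.91, adjusted p = 0.00582), as were T and NK cell markers, at -0.76 (adjusted p = 0.0933; median -1.26, adjusted p = 0.00166 without that array).

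The count of 16 fell to 0 without either BCR/ABL array, without imatinib replicate 1, with only the vector and imatinib arrays in the model or with a variance prior not tied to signal, to 3 with 64 as the added constant and to 10 without imatinib replicate 2. It was 30 without vector replicate 1 and 54 (19 higher and 35 lower) without vector replicate 2, rose to 275, 201 higher and 74 lower, with array medians, to 188 and 181 with the filters, to 78 with 1 as the added constant and to 28 with a robust prior, and fell to 9 with the replicate number as a block.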

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

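The test of unnamed probe sets was fixed before the data were examined only as a setting that adds them to the model; looking at them on their own was chosen afterwards. Of 9160 probe sets without a gene symbol, 1 was called in BCR/ABL against vector, higher by 2.47 on the log2 scale, and 0 in the other comparisons, where limma's adjustment ran over the named and unnamed probe sets together. This signal lies outside the named probe sets on which the comparisons rest. Groups of 2 arrays were too small to test single arrays as outliers or to compare other splits of the samples.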

How the results depend on the processing

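Array weights were the setting chosen after the data were seen. The counts of called probe sets, 22, 0 and 16 for BCR/ABL against vector, imatinib against untreated BCR/ABL, and BCR/ABL with imatinib against vector, became 298, 1200 and 275 with array medians. They became 189, 142 and 188 above the 30th percentile of mean signal and 132, 211 and 181 above the 50th, where fewer probe sets are tested. With 1 as the added constant they were 83, 3 and 78, with 64 they were 18, 0 and 3, and with a robust prior 42, 0 and 28. With a variance prior not tied to signal they were 0, 0 and 0, against 4121, 5238 and 4949 at an unadjusted p under 0.05 in the limma test reported. With only the 2 groups compared they were 17, 0 and 0, and with array weights 19, 17 and 13. Leaving out each array in turn gave 0 to 38, 0 and 0 to 54, where the lone array of a group was assumed to vary like the others. The values as deposited and all probe sets with or without a symbol gave counts within 1.5 times. The filtered probe sets were also fitted anew, so their p-values changed too. With imatinib against untreated BCR/ABL, limma's smallest adjusted p went from 0.0815 to 0.0147 above the 30th percentile, more than fewer tests alone can give. The cause of the shifts in these counts was not tested.

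With the replicate number as a replicate block the counts were 22, 0 and 9, of which 15 and 8 were among the 22 and 16. Deviations of arrays with the same number correlated at -0.08 between vector and BCR/ABL, 0.16 between vector and imatinib, and 0.146 between BCR/ABL and imatinib. The arrays were not treated as paired, because no label says what the number marks. Both control ratios were higher in replicate 1 than in replicate 2 of each group, so a batch shared by number is not excluded. With the block 0 probe sets were called lower, and Trp53inp1 in BCR/ABL against vector (adjusted p = 0.0734) and Sdc1 with imatinib against vector (adjusted p = 0.0804) were not called, nor were Il6 (adjusted p = 0.0584) and Tpsab1 (adjusted p = 0.0998) in the same comparisons. Calls also ended for Timp1, Akr1c19, Car4, Lat and the Enah probe set with 4.66 in BCR/ABL against vector. With imatinib against vector they ended for Akr1c12, Akr1c13, Mcpt2, Plxdc2 and Podxl.

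Of 36 called gene values, 0 changed sign under any of 14 settings. All 36 stayed past the threshold with array medians, an added constant of 1 or a robust prior, 34 with the values as deposited, 19 with a constant of 64 and 11 with only the 2 groups compared. Without an array the number was 17 for vector replicate 1, 10 for vector replicate 2, 10 and 15 for imatinib replicates 1 and 2, and 0 for either BCR/ABL array. The lists called, 11, 9 and 16, were 0, 0 and 0 with an estimated correlation and 3, 0 and 2 by fry. Without single arrays 5 to 10 lists were called with imatinib against untreated BCR/ABL. These other tests aside, 7, 3 and 10 lists kept their call under all 14 settings. The median of monocyte and macrophage markers in BCR/ABL against vector, 0.228 and not called, ran from -0.565 without vector replicate 2, where it was called lower, to 1.167 without vector replicate 1.

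The slope of return, -0.101, was -0.114 with the values as deposited, -0.109 with array medians, -0.104 and -0.103 above the 30th and 50th percentiles, -0.096 with unnamed probe sets, -0.061 and -0.114 with constants of 1 and 64, -0.117 with a minimum change of 0.5, -0.133 with none and -0.288 with shared arrays. Shared arrays lower it by construction; the cause of the other shifts was not tested. Between 36.1% and 41.5% of probe sets per array lay below a signal of 16, where changes are compressed.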

Other observations

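Of 29 gene families picked by name, all were looked at after the data were seen, and the pattern for tRNA synthetases was widened afterwards. Of the tests, the second mast cell list and the MYC-linked list were written before their values were seen, although related results already pointed to their directions; the other 5 were chosen afterwards. The test of a lower share of the main cell type was also revised after its values were seen: its first rule, the excess of mast cell over other markers, excluded that explanation on 4 lists but gave -0.051 on all 7 and no longer did, and the rule used instead asks whether any other marker list fell. The tests of RNA quality and scaling were narrowed after their values were seen. With imatinib against untreated BCR/ABL, of 76 mitochondrial ribosomal protein genes 74 were lower (median -0.46, adjusted p = 2.53e-25 by camera over the 29 families; adjusted p = 0.0890 with an estimated correlation). Of 40 proteasome genes 38 were lower (median -0.34, adjusted p = 6.49e-15), as were 15 of 16 cytosolic tRNA synthetase genes (median -0.56, adjusted p = 1.28e-10), 76 of 86 respiratory chain and ATP synthase genes (median -0.19, adjusted p = 6.62e-12) and 22 of 26 RNA polymerase genes (median -0.36, adjusted p = 8.77e-06), each with adjusted p = 0.129 with an estimated correlation. Nucleoporin genes were lower in 19 of 19 (median -0.42, adjusted p = 9.51e-07; adjusted p = 0.141 with an estimated correlation). The 49 cytosolic ribosomal protein genes had a median of -0.01 (adjusted p = 0.568), or -0.002 relative to all genes; its sign turned under another scaling only with the shift of all genes. The difference between the mitochondrial and cytosolic families was not tested.

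The 5 Ypel genes, whose functions are little known, were all higher with imatinib than without (median 0.92, adjusted p = 0.000355; adjusted p = 0.129 with an estimated correlation) and all lower in BCR/ABL than in vector (median -0.54, adjusted p = 0.0367; adjusted p = 0.376 with an estimated correlation). The Akr1c family of 9 genes had a median of 1.73 in BCR/ABL against vector (6 higher and 3 lower, adjusted p = 2.21e-05; adjusted p = 0.376 with an estimated correlation) and -0.73 with imatinib (adjusted p = 0.00248; adjusted p = 0.129 with an estimated correlation). The untreated BCR/ABL arrays enter both changes with opposite sign, so opposite directions also arise by chance. These directions held under each scaling tried.

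Mast cell and basophil markers were higher in both BCR/ABL groups. A lower share of the main cell type would raise markers of every other type. B cell markers changed by -0.932 or less in each of 4 pairs of BCR/ABL and vector arrays, so a lower share alone does not account for all lists. That fall was known when the rule was chosen and may have a source of its own. It therefore cannot decide whether a lower share raised the mast cell markers. Granulocyte and megakaryocyte markers were higher (medians 0.58 and 0.98), and a lower share beside other changes stays open. RNA quality cannot be told apart, since the control ratios depend on a labelling that is not settled. The beta-actin ratios with imatinib (1.74 and 1.55) and in vector (1.81 and 1.62) overlapped, yet the list differed by 2.987 between these groups. Cells of mast or basophil lineage, or their RNA, may have been in the sorted samples: of 19 genes on a second list 16 were higher, with a median of 0.429 (camera p = 5.53e-06; p = 0.0418 with an estimated correlation), Slc6a4 changed by 2.82, and the abundant transcripts Srgn and Fcer1g by 0.11 and 0.43. The sort for c-Kit and Sca-1 without lineage markers need not remove mast cells, which carry c-Kit. It would be expected to remove basophils, which largely lack c-Kit. Expression of these marker genes by the stem cells themselves stays open. Cells of mast or basophil lineage, if present, could also contribute to other genes called higher and to the cytokine and lipoxygenase lists. That was not tested.

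Ribosome biogenesis genes were lower with imatinib. Relative to all genes the list median was -0.41 or lower in each of 4 pairs of arrays, quantile normalized or as deposited. A scale shift common to all genes would not give such a difference. Camera, by which the list was picked, already compares it with other genes, so this value is not separate evidence. A shift that depends on signal level stays open. RNA quality cannot be told apart, since the labelling behind the control ratios is not settled. The list median was also -0.368 between imatinib and vector, whose beta-actin ratios overlapped. A weaker MYC-linked growth programme is a candidate explanation: on a separate list of MYC-driven genes 22 of 23 were lower, with a median of -0.544 (camera p = 9.29e-15; p = 0.0320 with an estimated correlation), while Myc itself changed by -0.15 (adjusted p = 0.568). A slower growth of the cells for other reasons stays open and was not tested.

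B cell markers were lower in both BCR/ABL groups, and vector replicate 1 had the highest values. RNA of B lineage cells in that array alone could account for the list's change only if the other vector array matched the BCR/ABL groups. Against vector replicate 2 the list median was -1.743 and -0.932 in the BCR/ABL arrays and -2.461 and -2.339 with imatinib, which argues against that array as the whole source. Vector replicate 1 lay 2.363 above replicate 2, so it may account for part. Fewer B-primed cells among BCR/ABL stem cells, or more B lineage cells in both vector samples despite the lineage sort, stay open and were not tested.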
